A study of Homo sapiens with 10 samples.

How the data were processed

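Gene expression was measured by sequencing of poly(A)-selected RNA in 10 libraries from D425 and HD-MB03 cells. Per the labels, stable polyclonal populations carried a doxycycline-inducible lentiviral vector, empty or with a hairpin against CRX, and doxycycline was given at 4 µg/ml over 72 h. A pair of hairpins was used, and the labels do not say which hairpin each library carries, so the shCRX libraries of a line were treated as 1 group. The deposited values were read counts per gene, 1 file per library, made by the authors with HTSeq and not normalised. Per the submitters' processing notes, bcl2fastq, HISAT2, HTSeq and DESeq2 were used with the human build GRCh37, also called hg19, with versions not given in the sources used here. The reference annotation used here was of another build, so it served for gene symbols, gene types, GC content and transcript length alone and no positions are given.

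Each file held 57820 gene identifiers, of which 52338 were given a symbol and 5482 were not, and 5 summary entries that were left out of library sizes and tests. Between 50.5% and 79.3% of all reads were counted in genes. The 37 mitochondrial genes held 0 counts in these files, so no mitochondrial share was computed. Between 1.96 and 18.06 M reads were counted per library, and a floor of 3 counts corresponded to 1.53 CPM in the shallowest library and 0.166 in the deepest. Poisson intervals and floors cover counting error alone. No pair of libraries held identical values (0 pairs), and every pair differed by more than sampling noise (chi-square per degree of freedom of 10.0 to 58.7 within groups). Levels are given as CPM, counts scaled by the effective library size. The Poisson intervals and the floor values above use unscaled library totals instead. Correlations of log2 CPM were 0.947 to 0.982 within an arm of a line, 0.933 to 0.959 between arms of a line and 0.791 to 0.864 between lines. The labels do not state that libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

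Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr on the 4 groups of line and arm, and a robust quasi-likelihood fit with 4 group means and 6 residual degrees of freedom. In all 16006 genes were tested, 425 of them without a symbol and with 0.829% of the reads, and the biological coefficient of variation was 26.0%. Tests were two-sided, and a gene passed with a Benjamini-Hochberg adjusted p under 0.05. Contrasts were the libraries labelled shCRX against controls in the mean of the lines, in D425 and in HD-MB03, the difference of these effects (D425 minus HD-MB03), and D425 against HD-MB03 controls. Vector and parental libraries were compared in a fit with 6 groups and 4 residual degrees of freedom. D425 parental and shCRX libraries of the same replicate number had only that number in common. Across genes, the difference between the parental replicates and that between the same-numbered shCRX replicates had a correlation of 0.0137. No block was therefore used in the main tests.

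Gene lists of pathways, photoreceptor genes, medulloblastoma subgroup genes and markers of other cell types were fixed beforehand. Of 38 lists, 32 had at least 5 tested members and were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with the estimated correlation and fry as alternatives, adjusted over all lists of a comparison. CRX was a member of no list, and 9 fixed members could not be matched to a symbol in the annotation. Some lists share members, such as SMAD7 and TGFB1 in the TGF-beta component and response lists. Named genes were CRX and, among protein-coding genes that passed, had a mean of at least 1 CPM and showed no overlap of the arms within each line compared (not asked for the difference), the 12 largest rises and falls for the mean of the lines, 10 each for D425 and HD-MB03 and 8 each for the other comparisons. Up to 4 called members of each list with a called test or at least 3 called members, and every called member of the TGF-beta and photoreceptor lists, were added. The text names a selection of these genes, and the results of 2 of them are not reported here. Genes with 0 counts in a group are given as a bound against 3 counts over the group, and genes with 1 to 3 counts as a ratio with a counting interval. Reads of paralogs, pseudogenes and overlapping or antisense genes are uncertain, and the strand setting of the counting was not given in the sources used here.

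Groups, comparisons, gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except the correction for GC content and length and the thinning to equal depth, which were chosen after seeing the data. The alternatives were DESeq2 size factors or library totals in place of TMM, DESeq2 1.42.0 or limma-voom in place of edgeR, other filters on low counts, protein-coding genes alone, vector or parental libraries alone as control, each library left out in turn, D425 parental replicate 2 and the D425 vector library left out together because of a suffix in their names, the libraries compared alone, a test against 1.5-fold, and a replicate block in D425. On simulated counts with the same design, edgeR recovered genes with set changes in the right direction with 0 wrong signs, and called 0 genes of 15620 where none was set. These runs held no GC trend and no batch between libraries, so they do not cover calls that either would cause. Of the genes set to change 2-fold it recovered 52.2% in the mean of the lines, 34.3% in D425, 13.4% in HD-MB03 and 7.46% in the difference and between the control libraries, with 3 to 10 unchanged genes called per comparison. Most changes of that size outside the mean of the lines would be missed.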

Results

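RNA sequencing of poly(A)-selected RNA was compared in D425 and HD-MB03, a pair of cell lines from Group 3 medulloblastoma, a childhood tumour of the cerebellum. The question was which genes respond when CRX, a homeobox transcription factor of photoreceptors and the pineal gland, is lowered by short hairpin RNA, and whether genes of the TGF-beta and activin pathways are among them. D425 was represented by 2 parental libraries, 1 empty-vector library and 3 libraries labelled shCRX. HD-MB03 was represented by 1 parental library, 1 empty-vector library and 2 libraries labelled shCRX. Parental and vector libraries of a line served together as its controls, which gave 3 against 3 libraries in D425 and 2 against 2 in HD-MB03.

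In D425, 18.06 and 12.45 M reads were counted in genes in parental replicates 1 and 2, 11.36 M in the vector library, and 9.53, 4.73 and 3.64 M in shCRX replicates 1 to 3. The HD-MB03 parental and vector libraries held 2.08 and 1.96 M, and HD-MB03 shCRX replicates 1 and 2 held 14.55 and 14.26 M. Reads that did not align made up 30.9% and 26.4% of the HD-MB03 parental and vector libraries and between 4.54% and 7.99% of the other 8. Principal component analysis separated the lines on the first component, with 64.0% of the variance. The second component, with 10.0%, separated D425 shCRX and HD-MB03 control libraries from D425 control and HD-MB03 shCRX libraries. The same partition is given by the library numbers, which run from 20 to 62 in the first 5 libraries and from 110 to 136 in the others. Depth gives it too, with 1.96 to 9.53 M counted reads in the first 5 libraries and 11.36 to 18.06 M in the others. Within a line each number set held 1 arm only, so no value within a set could be had for any shCRX comparison, and batch and arm cannot be told apart within a line. A difference between the sets of equal size in both lines on the log2 scale would cancel in the mean of the lines and fall wholly on the difference between them. A set difference of unequal size would not cancel.

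**Figure D1:**
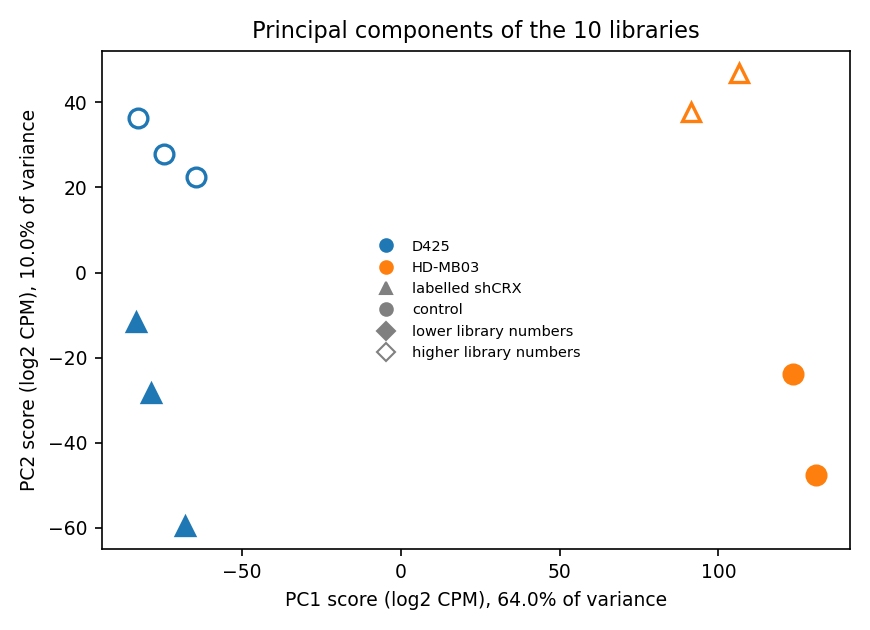
Scores of the 10 libraries on the first 2 principal components of log2 CPM, with colour for the line, shape for the arm and open symbols for the higher library numbers. The first component (64.0%) parts the lines, and the second (10.0%) parts the library-number sets, which hold opposite arms in the lines.

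CRX, the targeted gene (ENSG00000105392.11), fell in the D425 libraries labelled shCRX and was higher, not lower, in the HD-MB03 libraries with that label. In D425 it dropped from 47.4 ± 17.6 to 22.2 ± 2.74 CPM (SD, n = 3 and n = 3), and all 3 shCRX libraries lay below all 3 controls. The log2 fold change was -1.10 ± 0.26 (SE, 95% interval -1.67 to -0.53, edgeR adjusted p = 0.0436). In HD-MB03 the mean was 12.4 ± 0.113 in the controls and 25.6 ± 3.00 in shCRX (SD, n = 2 and n = 2). The log2 fold change there was 1.04 ± 0.36 (SE, 95% interval 0.26 to 1.83, edgeR adjusted p = 0.174). The intervals of both lines are not adjusted for the number of genes tested. The HD-MB03 value rests on 47 counts in the controls and 716 in shCRX, with exact Poisson 95% intervals of 8.55 to 15.5 and 23.1 to 26.7 CPM. Any direction given below for HD-MB03 therefore follows the label, against which CRX itself went. The response of CRX differed between the lines by -2.14 ± 0.45 on the log2 scale (edgeR adjusted p = 0.0199), and its mean over both lines was -0.03 ± 0.23 (edgeR adjusted p = 0.978). A two-sided exact permutation test gave p = 0.1 in D425 and p = 0.333 in HD-MB03, the smallest values that 3 against 3 and 2 against 2 libraries allow. The call in D425 stood close to the threshold. It was kept without D425 parental replicate 2 (-1.38) and lost without any 1 of the other 9 libraries, with fold changes from -1.22 without D425 shCRX replicate 3 to -0.81 without the D425 vector library, which held the highest level of 64.9 CPM. The call of the difference was lost without the HD-MB03 parental library (-2.18), the HD-MB03 vector library (-2.17) or HD-MB03 shCRX replicate 1 (-2.03), and with limma-voom (-2.06), vector controls alone (-2.61) or parental controls alone (-1.84).

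**Figure D2:**
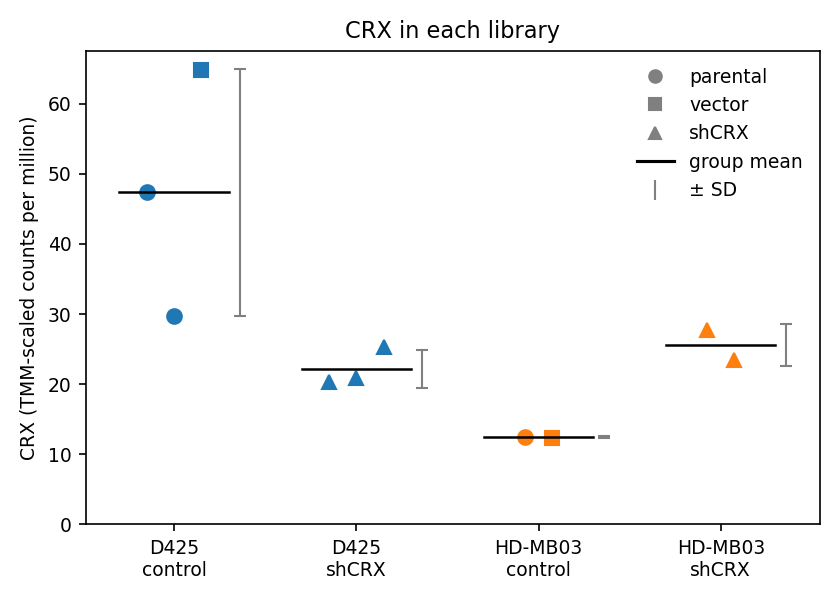
CRX in each of the 10 libraries in TMM-scaled CPM, with circles for parental, squares for vector and triangles for shCRX libraries, a line for the group mean and a bar for ± SD. D425 shCRX libraries lie below D425 controls (22.2 against 47.4), and HD-MB03 shCRX libraries lie above HD-MB03 controls (25.6 against 12.4).

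The libraries labelled shCRX and the controls were also compared in the mean of the lines, although CRX went against the label in HD-MB03. Genes that fell included IGFBP2, which encodes a binding protein of insulin-like growth factors, IGSF11, a cell adhesion molecule, CCND2, which encodes cyclin D2, and SPOCK1, an extracellular matrix proteoglycan. IGFBP2 fell by 3.12 ± 0.32 on the log2 scale (SE, edgeR adjusted p = 0.00297), from 20.6 ± 7.02 to 0.410 ± 0.386 CPM in D425 (SD, n = 3 and n = 3) and from 124 ± 24.7 to 80.8 ± 8.72 in HD-MB03 (n = 2 and n = 2). The log2 fold change was -2.77 ± 0.33 for IGSF11 (edgeR adjusted p = 0.00714), -2.67 ± 0.36 for CCND2 (edgeR adjusted p = 0.0147) and -1.51 ± 0.21 for SPOCK1 (edgeR adjusted p = 0.0138). PFKP, a phosphofructokinase of glycolysis, and IRS1, an adaptor of the insulin receptor, also fell, with log2 fold changes of -0.96 ± 0.16 and -0.90 ± 0.16 (edgeR adjusted p = 0.0376 and 0.0459). LRFN5, a synaptic adhesion molecule (-2.22), CACNG5, a calcium channel subunit of the TARP family (-1.64), MOCS1, of molybdenum cofactor synthesis (-0.98), RPL36AL (-0.84) and the cyclin gene CCNK (-0.73) fell as well. Of the genes named, IGSF11, SPOCK1 and RPL36AL passed in each line, IGFBP2, CCND2, LRFN5, CACNG5, MOCS1 and IRS1 passed in D425 and not in HD-MB03, and PFKP and CCNK in HD-MB03 and not in D425. IGFBP2 and CCND2 fell more in D425 than in HD-MB03, by the test of the difference (-5.00 and -2.89, edgeR adjusted p = 0.00135 and 0.0444), and the others did not pass that test.

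In total 36 genes passed in the mean of the lines, 3 higher and 33 lower. This excess of lower genes was not kept without HD-MB03 shCRX replicate 1, and was kept in the other settings. The 3 higher genes of the 36, named after their values were seen, were MBNL3, a splicing regulator (1.36 ± 0.20, edgeR adjusted p = 0.0169), SYDE1 (1.39 ± 0.24, edgeR adjusted p = 0.0455) and a processed pseudogene. Among the fixed gene lists, 2 of 39 cytosolic ribosomal protein genes fell, RPL8 (-1.03 ± 0.14) and RPS9 (-0.86 ± 0.15). Both were near 0 in D425 alone (-0.05 and -0.09), and reads of this family are shared with pseudogenes. The ribosomal list ranked low by camera (adjusted p = 4.68e-04; adjusted p = 0.932 with an estimated correlation), and adjusted over the list alone 1 member was higher and 4 were lower. Replication-dependent histone genes ranked low with 0 of 14 called by edgeR (camera adjusted p = 8.33e-04; adjusted p = 0.928 with an estimated correlation), and adjusted over the list alone 1 was lower. Their median was 0.50 in D425, with 10 of 14 positive, and -1.99 in HD-MB03, where the share of reads that did not align was 30.9% and 26.4% in the controls and 5.001% and 6.49% in shCRX. Hypoxia and glycolysis genes ranked low with PFKP alone called of 30 (camera adjusted p = 0.0229; adjusted p = 0.928 with an estimated correlation), and 2 were lower adjusted over the list alone. BMP genes ranked high with 0 of 21 called by edgeR (camera adjusted p = 0.0493; adjusted p = 0.928 with an estimated correlation), a call that was also lost with DESeq2 size factors, and 2 were higher adjusted over the list alone. The count of 36 became 18 without D425 parental replicate 1, 14 without the D425 vector library, 15 without the HD-MB03 parental library, 16 without the HD-MB03 vector library, 71 without HD-MB03 shCRX replicate 1 and 3 without HD-MB03 shCRX replicate 2. It was 1 with vector libraries alone as control, 2 with parental libraries alone, 67 after correction for GC content and length, and 401 by DESeq2.

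In D425, genes of photoreceptors fell in the libraries labelled shCRX. PDC, which encodes the phototransduction regulator phosducin, fell from 70.9 ± 32.9 to 0.417 ± 0.378 CPM (SD, n = 3 and n = 3), a log2 fold change of -7.13 ± 0.63 (SE, edgeR adjusted p = 5.85e-04). GUCA1B, a guanylate cyclase activator, fell by 3.91 ± 0.50 (edgeR adjusted p = 0.00216), and GNGT1, the rod transducin gamma subunit, by a log2 fold change of -2.58 ± 0.29 (edgeR adjusted p = 9.34e-04). The polarity gene CRB1 (-2.77), the ciliary genes RP1L1 (-2.48) and MAK (-1.50), the rod phosphodiesterase gene PDE6A (-1.20), the matrix proteoglycan gene IMPG2 (-0.92), PROM1 of outer segment discs (-0.89) and EGFLAM of the photoreceptor synapse (-0.80) fell as well. In all, 10 of the 73 tested members of the photoreceptor lists fell.

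By list, 6 of 39 phototransduction and outer segment genes fell (camera adjusted p = 1.97e-05; adjusted p = 0.439 with an estimated correlation), and adjusted over the list alone 2 were higher and 9 lower. Of 21 photoreceptor matrix and synapse genes, 4 fell (camera adjusted p = 0.118; 4 higher and 7 lower adjusted over the list alone). Of 13 photoreceptor transcription factors 1 rose, SAMD11 (3.15 ± 0.42, edgeR adjusted p = 0.00323), and the list did not pass (camera adjusted p = 0.325). Genes of the Group 3 classifier also ranked low, with 2 of 5 lower, GABRA5, a GABA receptor subunit (-1.85 ± 0.29, edgeR adjusted p = 0.00545), and IMPG2 (camera adjusted p = 4.11e-04; adjusted p = 0.351 with an estimated correlation; 3 lower adjusted over the list alone). Across genes, D425 fold changes rose with GC content (Spearman rho = 0.277), and 7 of the 10 photoreceptor genes still passed after that trend was removed. GUCA1B, RP1L1 and EGFLAM lay above the median GC content of 48.2%, the other photoreceptor genes that fell below it.

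Genes of the BMP and TGF-beta pathways rose in D425. INHBB, which encodes the beta B subunit of activin B and inhibin B, rose from 0.246 ± 0.0246 to 24.2 ± 28.8 CPM (SD, n = 3 and n = 3), a log2 fold change of 6.55 ± 1.02 (SE, edgeR adjusted p = 0.00732). The BMP antagonists GREM1 (5.34 ± 0.85, edgeR adjusted p = 0.00619) and NOG (2.36 ± 0.23, edgeR adjusted p = 5.85e-04), the BMP-induced transcriptional inhibitors ID3 (2.52 ± 0.35, edgeR adjusted p = 0.00327) and ID1 (2.29 ± 0.49, edgeR adjusted p = 0.0317), and the inhibitory SMAD genes SMAD7 (2.86 ± 0.40, edgeR adjusted p = 0.00323) and SMAD6 (2.01 ± 0.39, edgeR adjusted p = 0.0188) rose too. Of 21 BMP genes 6 rose (camera adjusted p = 1.67e-07; adjusted p = 0.318 with an estimated correlation; 10 higher adjusted over the list alone). Of 35 TGF-beta and activin response genes 3 rose, SMAD7, SPHK1 (2.51) and PMEPA1, which restrains TGF-beta signalling (1.65). That list ranked high (camera adjusted p = 5.44e-04; adjusted p = 0.318 with an estimated correlation), with 8 higher and 1 lower adjusted over the list alone. Of 31 TGF-beta and activin components 3 rose, INHBB, SMAD7 and the latent TGF-beta binding protein gene LTBP3 (1.84), and the list did not pass (camera adjusted p = 0.0645; 5 higher and 1 lower adjusted over the list alone). The GC content of these genes was 53.8% in PMEPA1 to 67.8% in LTBP3, above the median of 48.2%, except for GREM1 at 39.8%, so the GC trend of rho = 0.277 ran in the direction of the rises other than GREM1. After that trend was removed, all 5 lists that camera called in D425 were still called, the BMP and TGF-beta response lists among them.

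Further rises in D425 included the homeobox gene PRRX2 (6.54), C4orf48 (5.64), the polysialyltransferase gene ST8SIA2 (5.24), RFLNA (4.90), the ETS factor ETV4 (4.76), RAB5IF (4.60) and SRXN1, an oxidative stress gene (4.55). FEM1A held 32 counts in shCRX and 1 in the controls, a 67.4-fold ratio with a counting interval of 11.3 to 2745. EPHA3, an ephrin receptor, was at least 55.2-fold lower (349 counts against 0), SLCO5A1, a transporter gene, at least 34.8-fold lower (220 against 0) and CD44, the hyaluronan receptor, at least 5.54-fold lower (35 against 0), with the floor at 3 counts over the group. HSD17B2, a steroid dehydrogenase, fell by 6.84 ± 0.45 (edgeR adjusted p = 2.41e-05). PID1 (-5.55), STAP1 (-4.51) and the mechanosensitive channel gene PIEZO2 (-4.25) fell as well, and ZNF141 held 52 counts in the controls and 1 in shCRX (24.7-fold, 4.24 to 993). Of 25 neuronal differentiation genes 3 fell, synaptophysin SYP (-1.69), CNTNAP2 (-1.91) and the sodium channel gene SCN2A (-1.96), without the list passing (camera adjusted p = 0.0645). Of 13 SHH pathway genes GLI2 (1.97) and SMO (1.09) rose and CCND2 (-4.11) fell (camera adjusted p = 0.273). Among 22 fibroblast and mesenchyme markers PDGFRB rose (1.199) and COL6A1 (-2.30) and ZEB2 (-1.64) fell (camera adjusted p = 0.419). Ribosomal protein genes were negative for 33 of 39 members, with 0 called by edgeR (camera adjusted p = 0.0140; adjusted p = 0.944 with an estimated correlation; 0 adjusted over the list alone).

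In D425 476 genes passed edgeR, 257 higher and 219 lower. The count was 217 without D425 parental replicate 1, 185 without the D425 vector library, 243 without D425 shCRX replicate 3, 54 without D425 parental replicate 2 and the vector library together, 21 with the vector library alone as control and 129 with parental libraries alone. Scaling by library totals shifted the median gene by 0.133 and gave 367 higher and 151 lower genes, thinning all libraries to equal depth gave 289, and DESeq2 called 986.

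**Figure D3:**
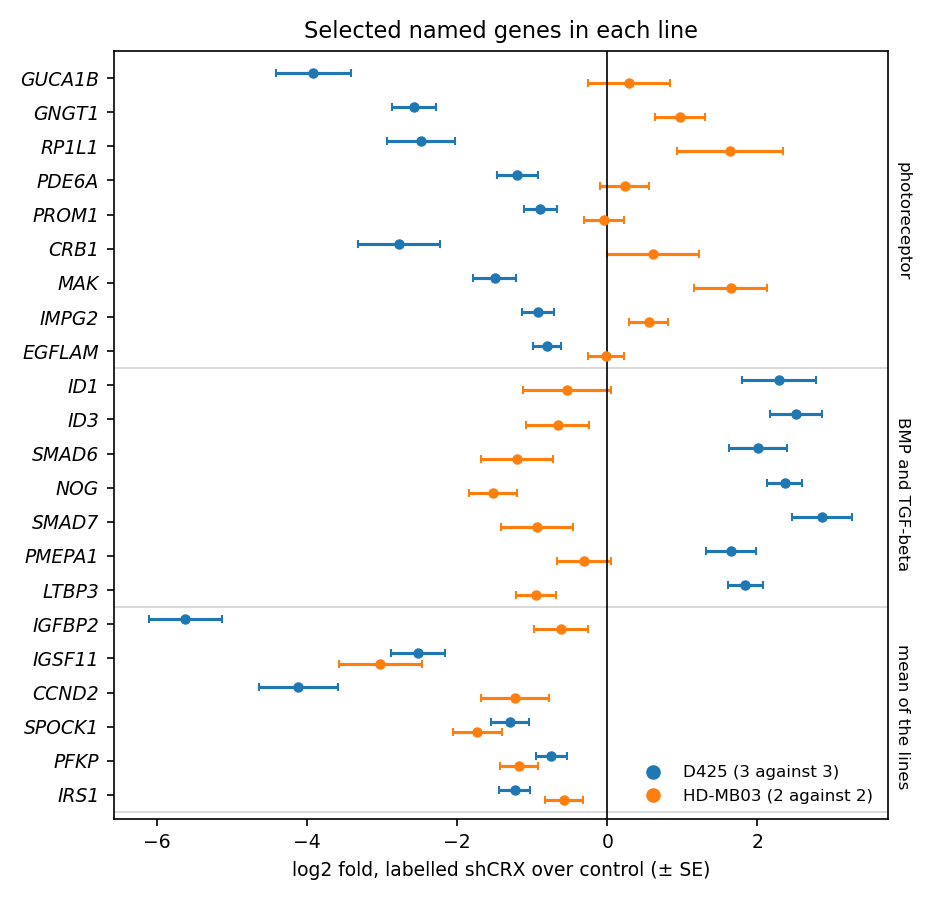
Log2 fold change of selected named genes, libraries labelled shCRX over controls, ± SE, in D425 (blue, 3 against 3 libraries) and HD-MB03 (orange, 2 against 2), grouped as photoreceptor genes, BMP and TGF-beta genes, and genes that passed in the mean of the lines. The photoreceptor genes drawn were taken from those that fell in D425, and the BMP and TGF-beta genes from those that rose there. Their side of 0 in D425 thus follows from the choice. SAMD11, a photoreceptor list gene that rose in D425, is not drawn. In HD-MB03 only NOG, IGSF11, SPOCK1 and PFKP of the genes drawn passed.

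In HD-MB03, where CRX was higher in the libraries labelled shCRX, SIX3, a homeobox gene of the forebrain and eye, and replication-dependent histone genes fell. SIX3 fell from 10.4 ± 8.81 to 0.215 ± 0.101 CPM (SD, n = 2 and n = 2), a log2 fold change of -5.50 ± 0.62 (SE, edgeR adjusted p = 0.00179). The linker histone gene H1-4 fell from 33.1 ± 17.2 to 0.823 ± 0.0494 CPM (-5.31 ± 0.95, edgeR adjusted p = 0.0190). H3C4 fell by 4.14 on the log2 scale, H1-5 was at least 24.6-fold lower (10 counts against 0), and H4C3 held 21 counts in the controls and 3 in shCRX (51.7-fold, 15.4 to 271). Most transcripts of this family lack a poly(A) tail, so poly(A) selection retains few of them, and its members share sequence. In all 4 of 14 histone genes fell (camera adjusted p = 1.78e-08; adjusted p = 0.313 with an estimated correlation; 9 lower adjusted over the list alone). The share of reads that did not align was 30.9% and 26.4% in the HD-MB03 controls and 5.001% and 6.49% in HD-MB03 shCRX, so it moved with this group of genes and with those that follow.

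TGFB1, the TGF-beta ligand gene, fell by 1.70 ± 0.34 (edgeR adjusted p = 0.0308) and the adhesion scaffold gene NEDD9 by a log2 fold change of -2.20 ± 0.48 (edgeR adjusted p = 0.0422). They were the only called members of the TGF-beta lists, as 1 of 31 components (camera adjusted p = 0.214) and 2 of 35 response genes (camera adjusted p = 0.361). NOG was the 1 BMP gene called of 21, at -1.52 (camera adjusted p = 0.333). None of the 13 photoreceptor transcription factors, 39 phototransduction genes or 21 matrix and synapse genes passed edgeR (camera adjusted p = 0.333, 0.897 and 0.914). CERKL, a gene of inherited retinal disease outside these lists, rose (1.62 ± 0.33, edgeR adjusted p = 0.0319). Other rises were the arrestin family gene ARRDC3 (2.32), SCML1 (2.16), ZNF708 (2.10), COMMD6 (1.91), HOOK1 (1.70), PBXIP1 (1.49), OGA, which encodes O-GlcNAcase (1.48), CNOT6L, of the CCR4-NOT deadenylase (1.38), and HIRIP3 (1.38). PDXP (-5.53), RAB5IF (-5.01), the mitochondrial nuclease gene ENDOG (-4.77) and PDF, a peptide deformylase (-4.74), fell. FEM1A was at least 46.8-fold lower (19 counts against 0), TMEFF1 held 15 counts against 2 (55.4-fold, 12.9 to 499) and SRXN1 17 against 3 (41.8-fold, 12.1 to 223).

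Ribosomal protein genes moved both ways in HD-MB03, with 2 higher and 4 lower of 39 (camera adjusted p = 0.188), among them RPL8 (-2.02), RPS9 (-1.64), RPL27 (-1.35) and RPL34 (1.26). Of 31 nuclear oxidative phosphorylation genes CYC1 (-1.44) and COX5A (-1.07) fell and ATP5PO (1.31) rose (camera adjusted p = 0.584). PFKP (-1.18) was the 1 called of 30 hypoxia and glycolysis genes (camera adjusted p = 0.0434; adjusted p = 0.673 with an estimated correlation; 1 higher and 1 lower adjusted over the list alone). Neural stem and progenitor genes were positive for 12 of 13 members, with 0 called by edgeR (camera adjusted p = 0.0110; adjusted p = 0.313 with an estimated correlation; 4 higher adjusted over the list alone). GLI2, a transcription factor of the SHH pathway, fell (-1.41).

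In HD-MB03 241 genes passed edgeR, 42 higher and 199 lower, and fold changes fell with GC content across genes (rho = -0.357). The excess of lower genes was not kept without a filter on low counts (404 higher and 386 lower). It was not kept without HD-MB03 shCRX replicate 1 either, and was kept in the other settings. The count was 31 without the HD-MB03 parental library, 82 and 15 without HD-MB03 shCRX replicates 1 and 2, 146 without D425 shCRX replicate 3, 30 with the vector library alone as control, 118 with the parental library alone, 106 without D425 parental replicate 2 and the D425 vector library, 141 with protein-coding genes alone and 495 with the HD-MB03 libraries alone. DESeq2 called 806.

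The lines differed in their response for many genes, and more genes moved in opposite directions than in the same one. Among genes that rose in D425, the difference was 10.01 ± 1.96 on the log2 scale (D425 minus HD-MB03) for PRRX2, 9.61 for RAB5IF and 9.37 for INHBB. The HD-MB03 part for PRRX2 rested on 11 counts in the vector library with 0 in the parental one. Without the vector library the difference was 2.13 and did not pass edgeR. The desmosome gene DSP (-7.16) and IGFBP2 (-5.00) differed the other way. BMP genes were higher in D425 relative to HD-MB03, with 4 of 21 called (camera adjusted p = 1.90e-04; adjusted p = 0.384 with an estimated correlation; 8 higher and 1 lower adjusted over the list alone). The TGF-beta component and response lists share SMAD7 and TGFB1, which count in each. TGF-beta components were higher too, with 5 of 31 (camera adjusted p = 0.0224, adjusted p = 0.384 with an estimated correlation, 6 higher adjusted over the list alone). Response genes were as well, with 5 of 35 (camera adjusted p = 0.00726, adjusted p = 0.384 with an estimated correlation, 8 higher and 1 lower adjusted over the list alone). Histone genes did so with 4 of 14 (camera adjusted p = 4.49e-04; adjusted p = 0.392 with an estimated correlation; 8 higher adjusted over the list alone).

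Phototransduction genes were lower in D425 relative to HD-MB03, with 1 higher and 4 lower of 39 (camera adjusted p = 0.0257; adjusted p = 0.723 with an estimated correlation; 2 higher and 8 lower adjusted over the list alone). Photoreceptor matrix and synapse genes gave 1 higher and 4 lower of 21 (camera adjusted p = 0.623). Neural stem genes ranked low with 0 of 13 called by edgeR (camera adjusted p = 0.0120; adjusted p = 0.384 with an estimated correlation; 7 lower adjusted over the list alone). GUCA1B, GNGT1, RP1L1, CRB1, MAK and IMPG2 passed the test of the difference, and PDC, PDE6A, PROM1 and EGFLAM did not. PDC had a mean of 0.0358 CPM in HD-MB03, with 0 counts in the controls, so its response there could not be judged. The median, the mean and the camera direction had the same sign in each list with a camera adjusted p under 0.05, in this and the other comparisons.

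For the difference 666 genes passed edgeR, 428 higher and 238 lower. The excess of higher genes turned without a filter on low counts (625 higher and 954 lower). It was not kept without the HD-MB03 vector library either, and was kept in the other settings. The count was 177 without the HD-MB03 parental library, 186 and 372 without HD-MB03 shCRX replicates 1 and 2, 376 without D425 shCRX replicate 3, 418 without D425 parental replicate 1, 345 after the correction for GC content and length, 189 without D425 parental replicate 2 and the D425 vector library, 55 with vector and 279 with parental libraries alone as control, and 1370 by DESeq2.

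IGSF11, SPOCK1, RPL36AL and the pseudogene RPL8P3 were the 4 genes that passed in both lines in the same direction, all lower, where independent lists would give 3.40. IGSF11 changed by -2.52 in D425 and -3.03 in HD-MB03, SPOCK1 by -1.29 and -1.73, and RPL36AL by -0.76 and -0.92. In opposite directions 43 genes passed, where independent lists would give 3.77, and 42 of them rose in D425 and fell in HD-MB03, NOG, GLI2, RAB5IF, ENDOG, PDF and PDXP among them. The 1 reverse case was an identifier without a symbol. Across genes, which are not independent replicates, the fold changes of the lines had a Spearman correlation of -0.143 and a Pearson correlation of -0.106 (covariance -0.121), and the lines share no control library. After the correction for GC content and length 3 genes moved the same way and 19 opposite ways, with a Spearman correlation of -0.0519, and after thinning to equal depth 3 and 18.

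**Figure D4:**
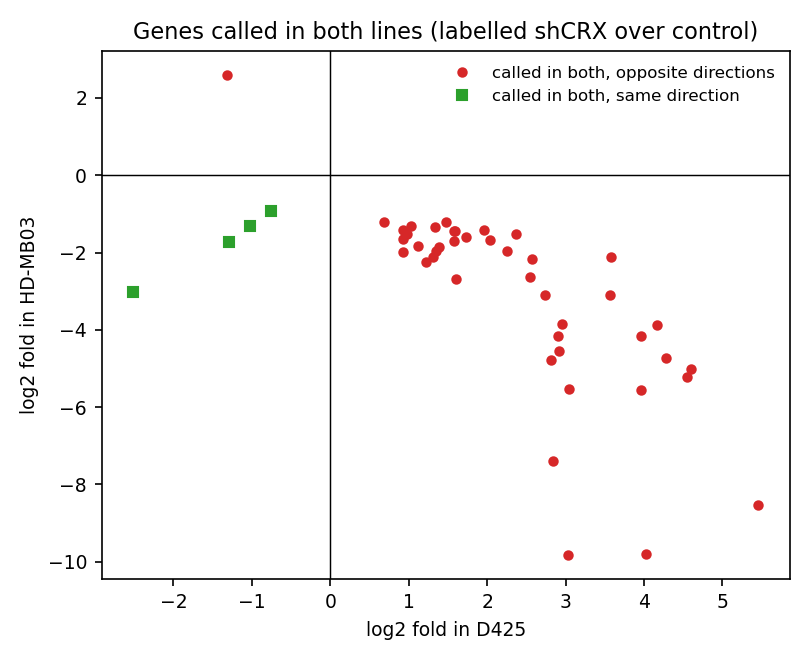
Fitted log2 fold change in HD-MB03 against that in D425, libraries labelled shCRX over controls, for each gene that passed in both lines, with green squares for the 4 genes of the same direction and red circles for the 43 of opposite directions. Fitted values of genes with 0 to 3 counts in a group, such as FEM1A, depend on the prior count, and their distance from 0 is no measured fold.

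Vector and parental libraries were compared over both lines, 2 against 3 libraries, to see whether the control kinds differed. By edgeR 0 genes passed, with 827 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.896, while DESeq2 called 7 and limma-voom 0. CRX was 0.36 ± 0.30 higher on the log2 scale in vector libraries, which did not pass (edgeR adjusted p = 0.896). Across genes, the vector minus parental fold changes fell with GC content (Spearman rho = -0.315). Within a line these libraries share arm and library-number set, so a GC trend of this size occurred without a difference in either. DNA replication genes were negative for 36 of 37 members (camera adjusted p = 5.68e-09), cholesterol synthesis genes for 21 of 25 (camera adjusted p = 7.04e-04) and SHH genes for 11 of 13 (camera adjusted p = 0.0236). Targets of p53 were positive for 21 of 28 (camera adjusted p = 7.04e-04) and genes of the ER unfolded protein response for 18 of 21 (camera adjusted p = 0.00794). All 5 lists had adjusted p = 0.969 with an estimated correlation, and adjusted over the list alone 0 members passed by edgeR in any of them.

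The control libraries of the lines were compared to describe the background of the knockdown, 3 D425 against 2 HD-MB03 libraries, each line from 1 tumour. The D425 controls were all in the set of high library numbers and the HD-MB03 controls both in the low one. From this comparison alone, line and set therefore cannot be told apart. Each set holds both lines, though with opposite arms, and no test of the lines within a set was made. The first principal component parted the lines in both sets. CRX was higher in D425 by 1.93 ± 0.35 on the log2 scale (SE, edgeR adjusted p = 0.00116). If the HD-MB03 labels were exchanged, its reference would be 25.6 in place of 12.4 CPM and this value would be smaller. Phototransduction genes higher in D425 included PDC, at least 94.0-fold, the recoverin gene RCVRN at least 44.2-fold, the guanylate cyclase gene GUCY2D at least 20.5-fold and CDHR1 by 4.56 ± 0.35, while PDE6B (-4.84) and the arrestin gene SAG (-4.01) were lower. In this list 17 of 39 were higher, 5 were lower and 17 were not called (camera adjusted p = 0.00404; adjusted p = 0.896 with an estimated correlation; 24 higher and 5 lower adjusted over the list alone). Of 21 matrix and synapse genes 9 were higher and 3 lower (camera adjusted p = 0.0928). Of 13 photoreceptor transcription factors 1 was higher, RAX2 at least 25.02-fold, and 5 were lower, among them NRL, the rod determinant (-3.15 ± 0.52), and NEUROD1 (-1.52) (camera adjusted p = 0.317).

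MAB21L2, a Group 3 classifier gene, was at least 327-fold higher in D425 (10679 counts against 0), but 2 of the 5 members of that list were lower, NRL and GABRA5, and the list did not pass (camera adjusted p = 0.861). Among the largest rises were the cancer-testis genes MAGEA3, at least 199-fold, CTAG2, at least 162-fold, and MAGEC1, at least 129-fold, with reads among near-identical copies uncertain. No list of such genes was tested. CNNM1 was at least 1213-fold, the cardiac homeobox gene NKX2-5 at least 574-fold and FOXQ1 at least 236-fold lower in D425, and so were the tyrosine kinase gene SYK (-10.51 ± 0.47) and the small heat shock protein gene HSPB1 (-9.57 ± 0.52). Integrated stress response genes were higher, 17 of 31 with 1 lower, including the asparagine synthetase gene ASNS (3.71 ± 0.72), the cystine transporter gene SLC7A11 (5.02) and DDIT3 (3.38) (camera adjusted p = 4.07e-04; adjusted p = 0.944 with an estimated correlation; 19 higher and 1 lower adjusted over the list alone). SHH genes were lower, 9 of 13, including CCND2 (-4.45 ± 0.44), BOC (-5.45) and CCND1 (35 counts in HD-MB03 and 1 in D425, 381-fold, 64.1 to 15488) (camera adjusted p = 5.61e-06; adjusted p = 0.188 with an estimated correlation; 9 lower adjusted over the list alone). NOTCH genes were lower for 7 of 16, including NOTCH1 (-5.54 ± 0.28; camera adjusted p = 0.00713; adjusted p = 0.392 with an estimated correlation; 1 higher and 7 lower adjusted over the list alone). Histone genes were lower for 12 of 14 (camera adjusted p = 3.01e-07; adjusted p = 0.392 with an estimated correlation; 12 lower adjusted over the list alone). The share of reads that did not align went with the groups here too, at 30.9% and 26.4% in the HD-MB03 controls and 4.54% to 5.88% in those of D425. TGF-beta components went both ways, with 5 higher and 9 lower of 31, including TGFB2 (-6.94) and INHBB (-6.91) (camera adjusted p = 0.0986), as did response genes with 6 higher and 10 lower of 35 (camera adjusted p = 0.691). INHBB went with the library-number sets, at 0.246 CPM in D425 control and 4.33 in HD-MB03 shCRX against 24.2 in D425 shCRX and 30.8 in HD-MB03 control libraries. In all 5486 genes passed edgeR, 2792 higher and 2694 lower, 2804 without the HD-MB03 parental library and 2937 without D425 parental replicate 2 and the D425 vector library.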

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

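The test of counting error in CRX and the ratio from held-out libraries were chosen after the results they bear on were seen, and the correction for GC content and length and the grouping of libraries by their numbers were chosen after seeing the data. The other tests were chosen before their own results were seen.

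Each value in the next paragraphs is a response to the shCRX label that differed between the lines by the edgeR test of the difference, 666 genes in all, and is given as the log2 response in D425 minus that in HD-MB03 or as the adjusted p of that test. CRX itself differed by -2.14, with a lower level in D425 and a higher one in HD-MB03 under the same label, so directions in HD-MB03 follow the label and not CRX.

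Among genes of the TGF-beta, activin and BMP lists the difference was 9.37 for INHBB, 4.12 for SPHK1, 3.88 for NOG, 3.80 for SMAD7, 3.22 for SMAD6, 3.18 for ID3, 2.79 for LTBP3, 2.78 for NEDD9, 2.32 for TGFB1, 1.95 for PMEPA1 and 1.36 for LTBP4. GREM1 was higher in D425 with an edgeR adjusted p of 0.0204, which rested on the HD-MB03 vector library and did not pass without it. As lists, BMP genes differed with a camera adjusted p of 1.90e-04, TGF-beta response genes with 0.00726 and TGF-beta components with 0.0224 (adjusted p = 0.384 with an estimated correlation for each).

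Among photoreceptor genes the difference was -4.20 for GUCA1B, -4.12 for RP1L1, -3.54 for GNGT1, -3.38 for CRB1, -3.15 for MAK, -1.85 for EYS, -1.78 for CDHR1 and -1.47 for IMPG2, and it was 4.05 for SAMD11, 1.49 for UNC119 and 1.34 for PLEKHB1. The phototransduction list differed with a camera adjusted p of 0.0257 (adjusted p = 0.723 with an estimated correlation). The retinal-disease gene CERKL differed by -2.34.

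Among histone and ribosomal protein genes the difference was 5.08 for H3C4, 4.70 for H4C8, 1.97 for RPL8, 1.62 for RPS15, 1.55 for RPS9 and -1.59 for RPL26. The adjusted p was 0.0375 for H1-5 and 0.0443 for H2AC20, both higher in D425 relative to HD-MB03. The histone list differed with a camera adjusted p of 4.49e-04 (adjusted p = 0.392 with an estimated correlation) and the neural stem list with 0.0120 (adjusted p = 0.384 with an estimated correlation). In other lists the difference was 3.37 for GLI2, 2.76 for PDGFRB, 2.71 for JAG2, 1.87 for NOTCH1, 1.56 for CYC1, 1.47 for COX5B, 1.43 for DLL3, 1.26 for COX5A, -2.26 for SYP and -2.89 for CCND2.

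Among the other named genes the difference was 10.01 for PRRX2, 9.61 for RAB5IF, 9.02 for PDF, 8.58 for PDXP, 7.58 for ENDOG, 6.68 for RFLNA and 6.03 for SIX3. For PRRX2 the HD-MB03 control counts lay in the vector library alone, and without it the difference was 2.13 and did not pass edgeR. It was -1.56 for OGA, -1.74 for HIRIP3, -1.75 for CNOT6L, -1.93 for PBXIP1, -1.996 for COMMD6, -2.20 for HOOK1, -2.27 for ZNF708, -2.57 for SCML1, -5.00 for IGFBP2, -5.38 for MTRNR2L6, a copy of a mitochondrial sequence, and -7.16 for DSP. With few or no counts in a group, FEM1A (adjusted p = 6.68e-04), SRXN1 (4.24e-04), BPIFB4 (0.00376) and TMEFF1 (0.00209) were higher in D425 relative to HD-MB03 by edgeR. HSD17B2 (adjusted p = 1.98e-04), SLCO5A1 (0.00226), ZNF141 (0.0129), TOX3 (0.0241), KBTBD8 (0.0379) and CD44 (0.0437) were lower.

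Of the genes that passed in both lines, 43 moved in opposite directions and 4 in the same one, against 3.77 and 3.40 from independent lists, and the median GC content was 63.2% for the opposite ones against 48.2% for all tested genes. A batch between the library-number sets of equal size in both lines, as the whole cause, needs a slope near -1 of HD-MB03 on D425 fold changes. Over the 476 genes called in D425 the slope was -0.33 (bootstrap 95% interval over genes -0.42 to -0.25), but choosing genes by their D425 call pulls it toward 0. The ratio of the HD-MB03 to the D425 difference from held-out D425 libraries ranged from -0.75 to -0.19. It lay above the bound of -0.5 in 33 of 36 combinations of libraries and not in the others, so such a batch cannot be told apart. A batch of unequal size needs no slope near -1 and was not tested. After each library's trend with GC content and length was removed, 345 genes were called in place of 666 (51.8% of that number), 299 of them among the 666. The 51.8% lies between the limits set for and against that trend, so its part cannot be told apart. Exchanged shCRX and control labels in HD-MB03 need no excess of genes moving the same way, and the 4 found (Poisson 95% interval 1.09 to 10.2) against 3.40 are consistent with an exchange, as is the direction of CRX; a batch by library number predicts the same. A different response of the lines to the hairpins stays open and was not tested, since library number, label and line leave no libraries to separate them.

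In D425, 10 photoreceptor genes fell. After the correction for GC content and length 7 still passed and the median of the 10 went from -1.99 to -1.96, while PROM1 (-0.89 ± 0.22 to -0.82 ± 0.21), PDE6A (-1.20 ± 0.27 to -1.11 ± 0.27) and IMPG2 (-0.92 ± 0.21 to -0.72 ± 0.23) moved toward 0 and lost their call. The 7 fell between the limits set beforehand, so by that count the trend as a cause cannot be told apart for these 3 genes. They kept most of their fall, and the median of the 10 hardly moved. These values argue against the trend as the cause of most of the fall. A batch by library number of equal size in both lines predicts the D425 median with opposite sign in HD-MB03. The 9 genes with at least 1 CPM there had a median of 0.55 (bootstrap 95% interval over genes -0.015 to 1.64) against -1.50 in D425. That interval leaves out the spread between libraries, and it holds the limit of 0.751, so such a batch cannot be told apart either. A response to lower CRX stays among the open explanations, since the D425 arms and the library numbers coincide.

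CRX was higher in the HD-MB03 libraries labelled shCRX, where the controls held few reads. The Poisson intervals of the summed counts lay 7.59 CPM apart, which argues against counting error as the cause. Exchanged labels and a batch by library number stay open, as does a different response of this line, which was not tested, and the 4 genes called in both lines in the same direction against 3.40 from independent lists leave an exchange of the labels possible.

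The 36 genes of the mean of the lines were set against other splits of the libraries within lines into groups of the same sizes. Of 60 splits, 3 gave at least as many genes, the real one included, so by this count chance was not excluded. The highest other split gave 666 genes, and it was the one that exchanges the arms of HD-MB03 and so follows the library-number sets. It is the same test as the difference between the lines, so the structure of the samples it points to is the one already given by those 666 genes, without support of its own. With this split left out, a choice made after its value was seen, 2 of 59 gave at least as many genes (3.39%), the real one included. The other one, with 62 genes, keeps the HD-MB03 arms apart and mixes those of D425, so it holds an arm difference. Splits that mix the arms of a line add that difference to the spread, so neither count measures chance. No arm difference within a line can be had inside a set. The next split gave 62 and the median of the others was 0. In D425 1 of 10 splits gave as many genes as the real 476, with 0 in the highest other, which are too few splits for a share under 0.05.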

How the results depend on the processing

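The corrections for GC content and length and for depth were chosen after seeing the data, the other alternatives before. Of 7127 recomputed values of named genes 5833 kept direction and side of the threshold, 1284 lost their call and 10 reversed; the cause of each change given here was not tested, except that fewer libraries or genes were used where named. For the mean of the lines 36 genes became 18 with library totals, 401 with DESeq2, 18 with limma-voom, 405 without a filter, 11 with protein-coding genes alone, 14 without the pair of D425 libraries with a suffix, 1 with vector and 2 with parental libraries alone as control, 8 for more than 1.5-fold and 67 after the GC and length correction, and ranged from 3 to 71 with single libraries left out. For D425 476 became 986 with DESeq2, 1211 without a filter, 54 without the suffix pair, 21 with vector and 129 with parental controls and 289 when thinned to equal depth, with 185 to 430 on leaving out single libraries. The replicate block over 4 numbered D425 libraries gave 42 genes, and the same 4 libraries without it gave 0. For HD-MB03 241 became 806 with DESeq2, 790 without a filter, 141 with protein-coding genes, 106 without the suffix pair, 30 with vector and 118 with parental controls and 495 with its own libraries alone, and ranged from 15 to 329 on leaving out single libraries. For the difference 666 became 1370 with DESeq2, 1579 without a filter, 189 without the suffix pair, 55 with vector and 279 with parental controls and 345 after the GC and length correction (177 to 841 on leaving out single libraries). Vector against parental gave 7 genes with DESeq2, 26 without a filter and 0 to 1 on leaving out single libraries, against 0 with edgeR, 827 genes at an unadjusted p under 0.05 and 0 with limma-voom. The controls of the lines gave 2937 without the suffix pair and 2804 to 6040 on leaving out single libraries. Where a library left out leaves 1 in an arm, that library is assumed to vary like the others.

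The fall of CRX in D425 lost its call with library totals (-0.96), limma-voom (-1.05), without the suffix pair (-1.17), with vector (-1.55) or parental controls (-0.81), with D425 libraries alone (-1.10), with the replicate block (-0.89) and in the same 4 libraries without it (-0.92), and ranged from -1.38 to -0.81 on leaving out single libraries, called only without D425 parental replicate 2. In HD-MB03 CRX was positive and not called in each alternative run. Its mean over the lines, not called, was 0.065 with library totals and 0.11 with parental controls, from -0.19 to 0.11 on leaving out single libraries, and 0.03 without HD-MB03 shCRX replicate 2. Vector minus parental CRX was -0.013 without the suffix pair and -0.020 to 0.74 on leaving out single libraries. Left-out libraries moved the SOX2 log2 fold, baseline controls of the lines, between -7.60 and 1.54 and that of MBP between -7.00 and 3.52, positive without the HD-MB03 parental library, and the ISG15 log2 fold, baseline controls, between -5.89 and 1.596, positive without the HD-MB03 vector library. With an estimated correlation 0 lists passed in the mean of the lines, D425, HD-MB03 or the difference, where camera at the preset correlation called 4, 5, 3 and 6, and fry called 0, 0, 0 and 2. After the GC and length correction 8 lists passed in D425. With vector controls the called lists of D425 were kept. Part of those called in the mean of the lines, in HD-MB03 and for the difference were lost. Genes moving the same way in both lines numbered 0 at an adjusted p under 0.01, 11 under 0.10 and 0 with vector controls, and genes moving opposite ways 6, 93 and 1, 19 after the GC and length correction and 18 when thinned. Thinned to equal depth, HD-MB03 gave 211 genes and D425 289. Simulated changes of 2-fold and 4-fold were recovered less often in HD-MB03, which had fewer control reads and fewer libraries, than in D425, and the effects of depth and of library number were not separated.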

Other observations

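The genes set against the library-number sets were picked after the data were seen, and no test was made on them; the other values here were computed as planned.

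Of 10 tested markers of glia and Mueller glia 1 fell in D425, the glutamate transporter gene SLC1A3 (-1.50 ± 0.28, edgeR adjusted p = 0.0144), and of 13 markers of other retinal cell types 1 fell there, the melanin synthesis gene DCT (-3.14 ± 0.36, edgeR adjusted p = 0.00117). Neither list passed in D425 (camera adjusted p = 0.885 and 0.138), and in HD-MB03 0 members of either passed edgeR (camera adjusted p = 0.914 for both; 1 glial marker higher and 0 retinal markers adjusted over the list alone). Of 5 immune and blood markers 0 passed edgeR in either line (camera adjusted p = 0.549 in D425 and 0.914 in HD-MB03; 0 adjusted over the list alone). Endothelial and epithelial markers had 4 tested members each, too few for a list test. The epithelial markers were positive for 4 of 4 in HD-MB03, with 0 passing edgeR, also adjusted over the list alone. KRT8 stood at 0.0715 and 22.1 CPM in HD-MB03 shCRX replicates 1 and 2, so its sign there rests on replicate 2. Of 35 genes of mitosis and G2/M, 0 passed edgeR in D425 (camera adjusted p = 0.837) and 0 in HD-MB03 (camera adjusted p = 0.735), and of 37 DNA replication genes 0 passed in either line (camera adjusted p = 0.991 and 0.734), with 0 adjusted over the list alone in each of these. Ribosome biogenesis and MYC target genes likewise gave 0 of 35 in D425 (camera adjusted p = 0.104) and 0 in HD-MB03 (camera adjusted p = 0.936). MYC was lower in D425 than in HD-MB03 controls by -0.83 ± 0.29 on the log2 scale (edgeR adjusted p = 0.0435). The D425 controls all had high library numbers and the HD-MB03 controls low ones. Line and library set therefore cannot be told apart for MYC from this comparison, and it was not tested between the lines within a set.

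Several genes were lower in each of the 5 libraries with higher numbers than in each of the 5 with lower numbers, whichever their line and label. RAB5IF was at most 0.968 CPM in the former and at least 10.9 in the latter, ENDOG at most 2.02 and at least 6.37, and FEM1A at most 0.0807 and at least 1.02. Of the 43 genes that passed in both lines in opposite directions, 37 showed no overlap between the library-number sets, which is how they would be picked, since the sets hold opposite arms in the lines.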
